A study of Mus musculus with 14 samples.

How the data were processed

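Gene expression was measured by RNA sequencing of MC-38 cells, a mouse colon cancer line, in 14 libraries that the labels place in 6 groups. In culture, 3 control libraries were set against 3 libraries of cells given chromatin of neutrophil extracellular traps (NETs), the DNA webs that neutrophils release. From lung tumours, MC-38 cells carrying green fluorescent protein were collected by flow sorting on day 30, with 2 libraries in each of 4 groups. The hosts were wild-type (WT) or lacked PAD4, the enzyme encoded by Padi4 that citrullinates histones during NET release, and each genotype was studied without surgery or with laparotomy on days 0 and 10. Total RNA was extracted with TRIzol, per the labels' protocols. The labels do not say whether libraries of a group came from separate cultures or animals, so p-values measure the spread between these samples, which may be technical.

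The deposited values are read counts per gene. Per the submitters' processing notes, Trimmomatic, STAR and the mouse build mm10 (GRCm38) were used; versions, options, the gene annotation and the library kit are not given in the sources used here. Each deposited table held 24411 gene symbols, 3 count columns (unstranded and one for each strand) and 4 summary lines that name no gene. The summary lines were left out of library sizes and tests. Over the 14 libraries, unmapped reads were 4.00 to 11.5% of all reads and multimapping reads 6.14 to 9.25%. Reads that matched no counted gene feature were 12.1 to 24.0%, and ambiguous reads 1.11 to 1.51%. For reads without a feature, the counts do not tell introns from sequence between genes. The first-strand column held 1.09 to 1.20% of the strand-specific counts. The unstranded column, in which reads of overlapping and antisense genes cannot be told apart, was used for the results, and the larger strand-specific column was an alternative. Total gene counts ran from 6.39 to 20.6 M in culture libraries and from 10.8 to 31.3 M in tumour libraries. Counts cover counting error only as far as reads are independent molecules; the deposited tables hold no molecular identifiers.

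Genes were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood test (filterByExpr with the groups, TMM factors, estimateDisp, glmQLFit with robust estimation, glmQLFTest), with Benjamini-Hochberg adjustment and a threshold of 0.05. The 6 culture libraries were fitted on their own (11753 genes tested). The 8 tumour libraries were fitted together in 4 groups (14615 genes tested), so that the 4 groups of 2 shared 1 estimate of the spread. Each fit had 4 residual degrees of freedom. The common biological coefficient of variation was 0.0633 in culture and 0.278 in tumours. The 6 comparisons were NET chromatin against control culture, laparotomy against control in each host, the difference between those 2 laparotomy effects (an interaction term), and PAD4 knockout (KO) against WT hosts without and with laparotomy. Standard errors of log2 fold changes were taken from the quasi-likelihood F statistic. Levels are CPM scaled with the TMM factors of the culture or of the tumour fit, with no count added; they are given as mean ± SD.

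Gene lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2, once with a preset correlation of 0.01 between genes and once with a correlation estimated from the data, with Benjamini-Hochberg adjustment over the lists with at least 3 tested members. The self-contained test fry was run beside it; it asks whether a list's genes move, on balance, one way, and does not compare them with other genes. The 33 lists covered 7 parts of lipid metabolism, 2 of energy metabolism, 13 cell responses and states, and markers of 11 other cell types or of sex. They held 578 genes, of which 574 were in the deposited tables. Gpat3, Ly6g, Ighm and Igkc were not matched. The 200 genes most clearly higher and the 200 most clearly lower with NET chromatin, by p, were also tested as sets in the tumour libraries.

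Comparisons, tests, gene lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule took, for each comparison, the 6 largest positive and 6 largest negative fold changes among genes past the threshold with a mean of at least 5 CPM and no overlap between the groups' libraries (no overlap rule for the interaction), leaving out predicted genes and pseudogenes. It also took the 2 members with the smallest p of each lipid list and of the 5 other lists with the smallest camera p, whether past the threshold or not, and Padi4. Not every gene that the rule took is printed. Members outside the rule that are named as examples of a list's count were chosen after their values were seen. Chromosome positions of named genes are from the GRCm38 annotation, in which all 138 symbols were matched.

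The tests were run on simulated counts drawn from the real means and library sizes with 200 genes changed. For NET against control (11735 genes), 71.6, 89.4 and 100% of genes changed 1.5, 2 and 4-fold were called, and 6.49% of 185 calls were false. For WT laparotomy (14502 genes) the shares were 5.97, 43.3 and 64.6%, with 6.25% of 80 calls false, and for the interaction (14484 genes) 0, 10.6 and 51.5%, with 16.3% of 49 calls false. A simulated 1.5-fold rise of the cholesterol synthesis list gave camera adjusted p of 0.00154, 0.0520 and 0.0629 with an estimated correlation in these 3 designs. Simulated genes were drawn independently of each other, while the estimated correlation within that list was 0.413 in the real NET comparison. The simulation therefore does not show how often a real, correlated list would be called. The alternatives were RLE size factors, no filter on low counts, the strand-specific column, DESeq2 1.42.0, limma-voom, a fit of all 14 libraries, a fit of the compared groups alone, the replicate number as a block, the pan-leukocyte marker score as a covariate, list sizes of 100 and 500 and each library left out in turn. Library totals without TMM were added after the data were seen. Replicates of a group differed by more than counting noise, with a chi-square per degree of freedom of 2.84 to 50.4 over genes with at least 20 counts, so none was counted as a repeat of another.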

Results

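The series asks how NETs released after surgery bear on the lipid metabolism of cancer cells, and its 14 libraries allow the question to be put in culture and in tumours. Gene counts summed to 8.79, 12.2 and 12.3 M in the control cultures and to 8.54, 6.39 and 20.6 M in the cultures given NET chromatin. In tumour cells they were 10.8 and 29.5 M from WT control hosts, 22.9 and 31.3 M from WT hosts with laparotomy, 27.0 and 26.2 M from KO control hosts and 15.0 and 15.3 M from KO hosts with laparotomy. The first axis of a multidimensional scaling plot parted the 3 NET cultures from the 3 controls and held 74.9% of the variance. In tumours the first axis held 38.1%, with WT control replicate 2 at one end and the 2 WT laparotomy libraries at the other. The second axis held 19.0% and set the KO control libraries, at -1.42 and -1.69, apart from the other tumour libraries (-0.02 to 1.22). Among replicates of a group, the WT control libraries lay farthest apart.

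Padi4 (chromosome 4, 140745865 to 140774236, GRCm38), the gene removed from the hosts, was read first. The sorted MC-38 cells carry their own intact Padi4, so its level does not check the host labels. Padi4 stood at 67.2 ± 4.3 CPM in control cultures and 65.3 ± 0.86 in NET cultures (SD, n = 3 each), with a log2 fold change of -0.04 ± 0.07 (SE; adjusted p = 0.669). Single tumour libraries held 3.20 and 7.49 CPM in the WT control group, 30.7 and 30.3 with laparotomy in WT hosts, 5.47 and 2.08 in the KO control group, and 3.97 and 2.83 with laparotomy in KO hosts. The log2 fold change of Padi4 with laparotomy was 2.48 ± 0.52 in WT hosts (adjusted p = 0.134) and -0.15 ± 0.52 in KO hosts (adjusted p = 0.924). The difference between these effects was -2.63 ± 0.73 (adjusted p = 0.125), and the KO against WT values were -0.53 ± 0.51 in controls (adjusted p = 0.648) and -3.16 ± 0.55 with laparotomy (adjusted p = 0.101). None of these passed the threshold in the edgeR fits of the 6 culture libraries or of the 8 tumour libraries with TMM factors and the filter on low counts. With library totals the NET value was -0.196 (adjusted p = 0.031), where the median of all genes was -0.156. In DESeq2 the WT laparotomy value (2.47), the difference (-2.62) and the KO against WT value with laparotomy (-3.16) passed, at adjusted p of 0.000148, 0.00961 and 6.42e-07. The fit of all 14 libraries called the same 3 values (adjusted p = 0.00375, 0.0123 and 0.00171). It pools the tumours with the cultures, whose common biological coefficient of variation was lower (0.0633 against 0.278). Its p-values for tumour comparisons may therefore be too small. The KO against WT value with laparotomy also passed in edgeR without the filter (adjusted p = 0.0385) and with the compared groups alone (0.0227).

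The first comparison asked which genes NET chromatin changes in cultured cancer cells. Il33 (chromosome 19, 29925114 to 29960718), an alarmin cytokine, rose from 0.390 ± 0.068 to 14.02 ± 1.56 CPM (SD, n = 3 each), a log2 fold change of 5.12 ± 0.24 (adjusted p = 9.8e-11). Tigit, an inhibitory receptor known from T and NK cells, rose by 3.35 ± 0.22, and Dynap by 3.12 ± 0.23. Nbl1, a BMP antagonist, rose by 2.91 ± 0.19, Padi2, a relative of Padi4, by 2.65 ± 0.19, and Acsbg1, an acyl-CoA synthetase, by 2.59 ± 0.21. Col6a2, a collagen VI chain, fell from 29.6 ± 2.4 to 4.30 ± 1.34 CPM (log2 fold change -2.73 ± 0.15, adjusted p = 7.2e-10). Chrnd, an acetylcholine receptor subunit, fell by 2.54 on the log2 scale, the scavenger receptor Scara3 by 2.31, the zinc finger genes Zfp189 and Rbak by 2.04 and 2.03, and the sulfiredoxin Srxn1 by 2.03.

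Over all genes, 6363 of 11753 (54.1%) passed the threshold, 3093 higher and 3270 lower, and 6985 had an unadjusted p below 0.05. At least 2-fold changes were found in 258 of the higher and 531 of the lower genes. The split depends on the scaling. With library totals in place of TMM, an alternative chosen after the data were seen, 1640 genes were higher and 4777 lower, the median log2 fold change of all genes was -0.156, and the medians of 8 of the 28 tested lists turned negative. Counts within lists moved with it, to 0 higher and 14 lower in fatty acid oxidation and 2 and 5 in both glycolysis and MHC class I presentation. They were 5 and 7 in immediate early genes, 6 and 8 in the unfolded protein list, 3 and 4 in eicosanoid synthesis and 4 and 11 in interferon response. The epithelial list passed with library totals (adjusted p = 0.0243). Changes are therefore given relative to the median gene.

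Genes of fatty acid synthesis were lower as a list with NET chromatin: 13 of 20 fell, 2 rose and 5 did not pass (median log2 fold change -0.28; camera adjusted p = 0.00687; adjusted p = 0.639 with an estimated correlation). The counts adjusted over the list alone were also 13 and 2. Elovl6 (chromosome 3, 129532355 to 129638495), which elongates palmitate, fell from 77.7 ± 6.5 to 36.0 ± 5.0 CPM (log2 fold change -1.09 ± 0.09, adjusted p = 1.1e-07). Acsl3 (chromosome 1, 78657825 to 78707743), which activates long-chain fatty acids, fell from 139 ± 0.47 to 82.7 ± 3.0 CPM (-0.75 ± 0.06, adjusted p = 9.8e-08). Acaca, the rate-limiting carboxylase, fell by 0.77 and Acss2, which makes acetyl-CoA from acetate, by 0.76, while the malic enzyme Me1 rose by 0.43 and Hsd17b12, a step of elongation, by 0.21.

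The other lipid lists did not pass as lists. In cholesterol synthesis, 12 of 24 genes fell, 1 rose and 11 did not pass (median -0.17, adjusted p = 0.0938; the same counts adjusted over the list alone). Sqle, squalene epoxidase, rose by 0.25. Among 19 genes of fatty acid uptake and lipid droplets, 7 rose and 9 fell both over all genes and adjusted over the list alone (median -0.33, adjusted p = 0.622). The fatty acid carrier Fabp5 rose by 0.90 and the lipase inhibitor Hilpda by 0.91, while the acyl-CoA synthetase Acsl1 fell by 0.76. In fatty acid oxidation 7 of 27 fell and 2 rose (6 and 2 adjusted over the list alone; median -0.05, adjusted p = 0.604), among them the peroxisomal enzyme Ehhadh, which fell by 1.52 (SE 0.24), and the nuclear receptor Ppard, by 0.51.

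In lipolysis and lysosomal lipid handling, 3 of 11 fell and 1 rose on both adjustments, that is, over all genes and adjusted over the list alone (adjusted p = 0.975). Psap, the saposin precursor, rose by 0.63 and Npc1, the lysosomal cholesterol exporter, fell by 0.58. Of 7 sterol efflux genes, 3 fell and 2 rose (4 and 2 adjusted over the list alone; median -0.27, adjusted p = 0.604), with the cholesterol exporter Abca1 lower by -2.06 ± 0.28 and the ubiquitin ligase Mylip by -0.68 ± 0.10. Of 11 genes of eicosanoid synthesis, 4 rose and 3 fell (5 and 3 adjusted over the list alone; median 0.16, adjusted p = 0.604), and both prostaglandin enzymes Ptgs2 (0.70 ± 0.06) and Ptgis (0.65 ± 0.12) rose.

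The lists higher as a group were oxidative phosphorylation, hypoxia, heat shock, cell cycle, pan-leukocyte and monocyte markers. In oxidative phosphorylation 18 of 34 genes rose and 1 fell, with medians of 0.20 over all and examples of 0.59 for Sdhd of complex II and 0.57 for Uqcrq of complex III (camera adjusted p = 0.00248; adjusted p = 0.639 with an estimated correlation). With library totals 9 of these 34 were higher and 4 lower. In hypoxia 12 of 17 rose and 1 fell (median 0.37; adjusted p = 0.0106; adjusted p = 0.79 with an estimated correlation), among them the histone demethylase Kdm3a (0.84 ± 0.11) and the endoplasmic reticulum oxidase Ero1l (0.77 ± 0.10). In heat shock 7 of 9 rose and none fell (median 0.41; adjusted p = 0.00687; adjusted p = 0.639 with an estimated correlation), with 0.92 ± 0.06 for the chaperone Hsph1 and 0.61 ± 0.08 for its partner Dnajb1. In cell cycle 16 of 27 rose and 4 fell (median 0.20; adjusted p = 0.0201; adjusted p = 0.639 with an estimated correlation). The replication genes Cdc6 (0.83) and Mcm4 (0.55) rose and the proliferation marker Mki67 fell by 0.83. Adjusted over the list alone, these 4 lists gave the same counts.

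Pan-leukocyte and monocyte markers were higher as lists in NET than in control cultures. Of 6 tested pan-leukocyte markers 5 rose over all genes and 6 adjusted over the list alone (median 1.80; camera adjusted p = 0.00151; adjusted p = 0.338 with an estimated correlation). All 10 markers of the list, tested or not, summed to 5.20 ± 0.50 CPM in control and 16.7 ± 0.86 CPM in NET cultures (SD, n = 3 each). Fcer1g, an Fc receptor chain, had 1 count over the control libraries and 73 over the NET libraries, a ratio of 76.2 with a counting interval of 13.3 to 3052. Cd53, a leukocyte tetraspanin, had 1 and 50 counts (ratio 52.2, interval 8.95 to 2104). Of 5 monocyte and macrophage markers 4 rose on both adjustments, over all genes and adjusted over the list alone (median 2.17; adjusted p = 0.00494; adjusted p = 0.338 with an estimated correlation). Lyz2, lysozyme, rose by 2.17 ± 0.19, and the macrophage receptor Adgre1, with 0 and 55 counts, was at least 19.1-fold higher, the bound that 3 counts over the control group allow.

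The remaining lists did not pass with NET chromatin. In NF-kB inflammation 6 of 26 rose and 8 fell (adjusted p = 0.975): the inhibitor Nfkbia rose by 1.18 and the chemokine Cxcl2 by 1.40, while Cxcl5 fell by 3.92 and Lcn2 by 1.28. In the NRF2 oxidative stress list 10 of 15 fell and 2 rose (median -0.30, adjusted p = 0.0504; past the threshold with RLE size factors at 0.04997), with Nqo1, a quinone reductase, down by -1.34 and Hmox1, heme oxygenase, up by 0.51. In the unfolded protein and integrated stress list 7 of 18 rose and 4 fell (adjusted p = 0.604), the chaperone Hspa5 by 1.29 and the pseudokinase Trib3 by -1.18. Higher and lower counts were 7 and 8 of 29 in interferon response (adjusted p = 0.968), 6 and 3 of 13 in MHC class I presentation (0.604), 5 and 3 of 17 in glycolysis (0.711), and 4 and 9 of 18 in mesenchymal genes (0.865). They were 3 and 0 of 4 epithelial genes (0.0613), 6 and 4 of 16 immediate early genes (0.711), 4 and 4 of 14 p53 targets (0.781), and 2 and 2 of 9 Wnt and stem cell genes (0.985). Neutrophil markers gave 2 and 0 of 3 (0.0938), dendritic 0 and 1 of 4 (0.704), fibroblast 3 and 2 of 6 (0.771), and erythroid and platelet markers 2 and 1 of 3 (0.809).

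Median, mean and test differed in sign for 7 lists of the NET comparison, none of them past the threshold. With an estimated correlation 0 of 28 lists passed in camera, with 2 below an unadjusted p of 0.05, and fry called 17. Reads that matched no counted gene feature were 22.6% ± 1.19 of all reads in NET cultures and 17.9% ± 0.33 in controls (SD, n = 3 each). Unmapped reads were 9.86% ± 1.52 and 6.55% ± 0.56. Each difference had an exact two-sided permutation p = 0.1, the smallest that 3 against 3 libraries allow (0.133 after Benjamini-Hochberg adjustment over 4 measures).

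**Figure D1:**
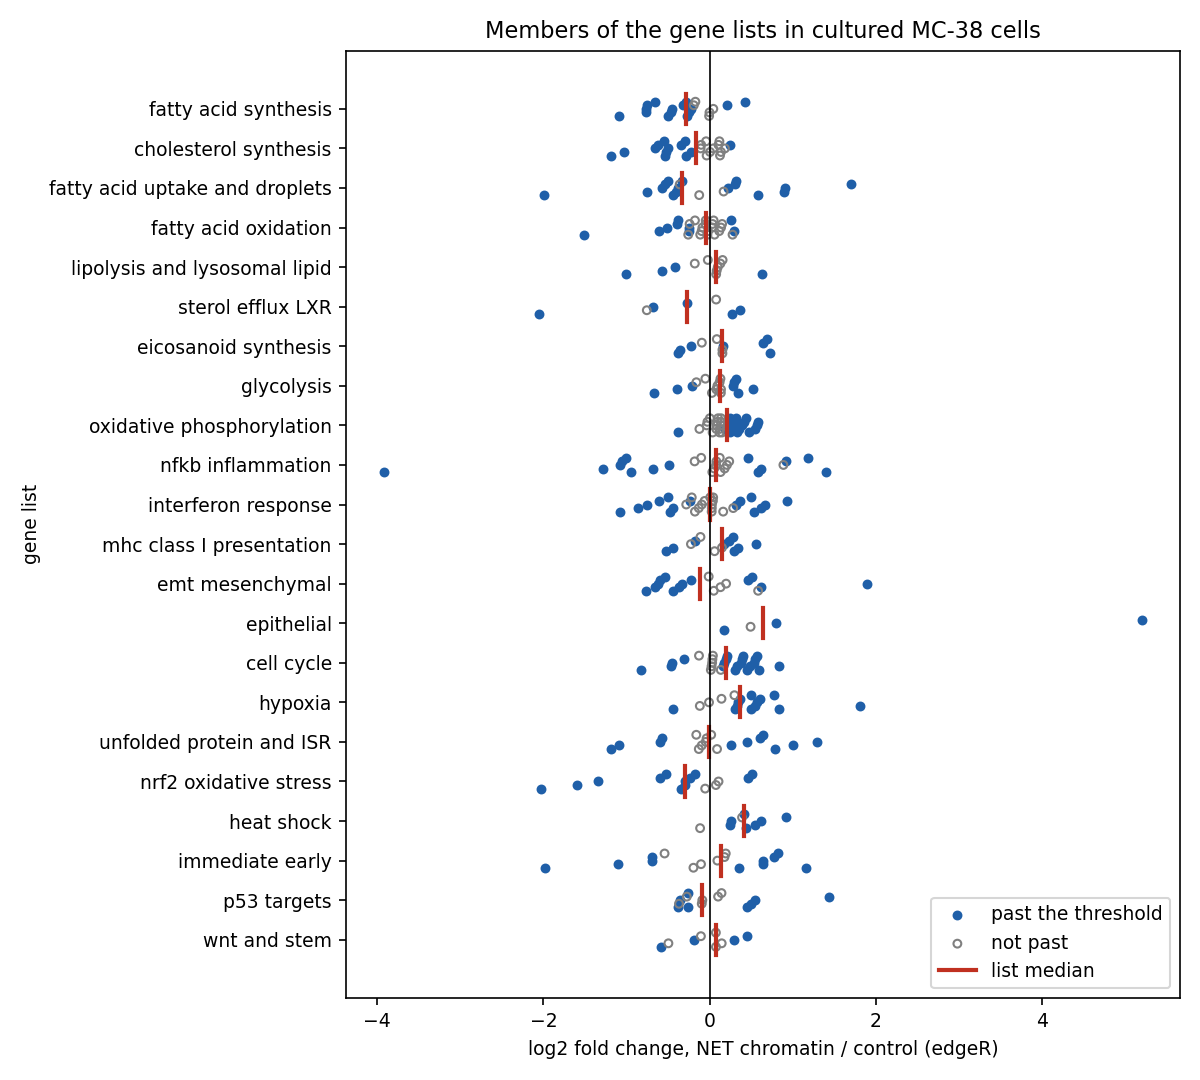
Log2 fold changes of the tested members of each gene list between NET and control cultures (3 libraries each); each point is a gene, filled if past the threshold, and the bar marks the list median. The fatty acid synthesis median lies at -0.28 and the oxidative phosphorylation median at 0.20.

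The next comparison asked what laparotomy changes in tumour cells of WT hosts. Tfrc, the transferrin receptor, rose from 262 ± 20 to 668 ± 4.7 CPM (SD, n = 2 each; log2 fold change 1.35 ± 0.15). Ero1l (chromosome 14, 45283087 to 45318771) rose from 216 ± 18 to 501 ± 74 CPM (1.21 ± 0.13) and Kdm3a by 0.87 ± 0.10, both genes of the hypoxia list. Lama4 (chromosome 10, 38965515 to 39110188), a laminin chain of vessel basement membranes, fell from 271 ± 54 to 66.2 ± 17 CPM (-2.03 ± 0.19). S100a16, a calcium-binding protein, fell by 2.73, Crip1 by 1.86, the inhibitory Fc receptor Fcgr2b by 1.72 and Ecscr, named for endothelial cells, by 1.14.

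These 3 higher and 5 lower genes, each at an adjusted p of 0.0317, were all that passed among 14615 in edgeR, with 2753 below an unadjusted p of 0.05. With the pan-leukocyte marker score as a covariate, 0 genes passed (edgeR, 1141 below an unadjusted p of 0.05). Markers of host cells were lower in the same libraries: per WT host group, summed lung epithelium markers went from 495 ± 491 to 22.1 ± 6.9 CPM, endothelial markers from 392 ± 344 to 57.7 ± 1.2, monocyte and macrophage markers from 1063 ± 943 to 127 ± 11, and pan-leukocyte markers from 511 ± 542 to 91.9 ± 19 (SD, n = 2). In WT control replicate 2 neutrophil markers without Padi4 summed to 603 CPM, against 57.5 in replicate 1.

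Hypoxia was the list with the clearest rise in WT hosts: 2 of 17 genes passed over all genes and 11 adjusted over the list alone, none lower (median 0.81; camera adjusted p = 3.12e-07; adjusted p = 0.412 with an estimated correlation). Glycolysis had 3 of 18 genes higher adjusted over the list alone and none over all genes (median 0.27, adjusted p = 0.000199; adjusted p = 0.412 with an estimated correlation), and cell cycle had none on either adjustment (median 0.19, adjusted p = 0.00226; adjusted p = 0.552 with an estimated correlation). Cholesterol synthesis had 3 of 24 higher and 1 lower adjusted over the list alone and none over all genes (median 0.17, adjusted p = 0.00679; adjusted p = 0.412 with an estimated correlation). Lss, which cyclises squalene epoxide, stood at 0.66 ± 0.15 (adjusted p = 0.135). Fatty acid synthesis had 3 of 21 higher adjusted over the list alone and none over all genes (median 0.25, camera adjusted p = 0.0176, or 0.412 with an estimated correlation). Acsl3 stood at 0.57 ± 0.15 and the desaturase Scd2 at 0.42 ± 0.10. In the same comparison, 330 genes at 10 CPM or more in every culture and at least 4-fold lower in KO controls had a median of 0.24, with 222 above 0. Apart from hypoxia, the list medians above were of that size. Whether these lists rose beyond a larger share of MC-38 RNA was not tested. Without WT control replicate 2 the lists of fatty acid synthesis (adjusted p = 0.140), cholesterol synthesis (0.0544) and cell cycle (0.498) no longer passed.

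The lower lists in WT hosts were largely markers of other cells. No member of these 13 lists passed over all genes in the edgeR fit of the 8 tumour libraries. Adjusted over the list alone, 12 of 13 lung epithelium genes (median -4.26, camera adjusted p = 1.14e-07), 15 of 17 monocyte and macrophage genes (-2.10, 1.14e-07), 9 of 11 endothelial genes (-3.95, 5.5e-06), 7 of 10 pan-leukocyte genes (-2.64, 0.000251), 6 of 7 B and plasma cell genes (-3.31, 0.00079), 6 of 8 dendritic genes (-3.17, 0.00262) and 2 of 11 fibroblast genes (-0.53, 0.0176) were lower. Of 11 neutrophil markers 8 were lower and 1, Padi4, higher (-5.02, 0.000137). Epithelial genes had 4 of 15 lower and 1 higher (-1.60, 0.00804). Interferon response had 6 of 30 lower (-0.39, 5.65e-06), MHC class I presentation 6 of 13 (-0.30, 6.79e-05), eicosanoid synthesis 10 of 17 with 1 higher (-1.22, 0.00226) and lipolysis 5 of 13 (-0.27, 0.011). All 13 had an adjusted p of 0.412 or 0.432 with an estimated correlation, where 0 of 33 lists passed in camera, 3 were below an unadjusted p of 0.05 and fry called 4. Calls were lost for interferon response (adjusted p = 0.124) and fibroblast markers (0.243) without WT control replicate 1, and for lipolysis (0.254) and epithelial genes (0.0537) without WT control replicate 2. They were also lost for lipolysis, epithelial genes (both 0.0771) and fibroblast markers (0.200) without WT laparotomy replicate 2. Alox5ap, which serves leukotriene synthesis, stood at -1.73 ± 0.26 (adjusted p = 0.0715) and Ptgs1, cyclooxygenase 1, at -1.88 ± 0.43 (adjusted p = 0.136).

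Lists that did not pass in WT hosts were uptake and droplets (median -0.19, adjusted p = 0.438), fatty acid oxidation (-0.10, 0.327), sterol efflux (-0.18, 0.274), oxidative phosphorylation (0.706), NF-kB inflammation (-0.03, 0.438), mesenchymal genes (-0.25, 0.063), T and NK cells (-1.22, 0.327), erythroid and platelet (-1.04, 0.0569) and Y-linked genes (-2.18, 0.0863). Stress and growth lists gave adjusted p of 0.847 (unfolded protein), 0.88 (NRF2 and heat shock), 0.643 (immediate early), 0.891 (p53) and 0.838 (Wnt), and 4 lists differed in sign between median, mean and test. The count of 8 genes was 512 without WT control replicate 1, 13 without WT control replicate 2 and 0 without either WT laparotomy replicate (edgeR, 1074 and 1304 genes below an unadjusted p of 0.05), and DESeq2 called 1207 and limma-voom 21. The 2 WT laparotomy libraries carried sample-sheet numbers 4 and 5, which WT control replicate 2 (4) and KO control replicate 1 (5) also carry. If a number is used once per sheet, the tumour libraries did not all stand on 1 sheet. A separate run of the WT laparotomy group cannot be told apart from the laparotomy.

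**Figure D2:**
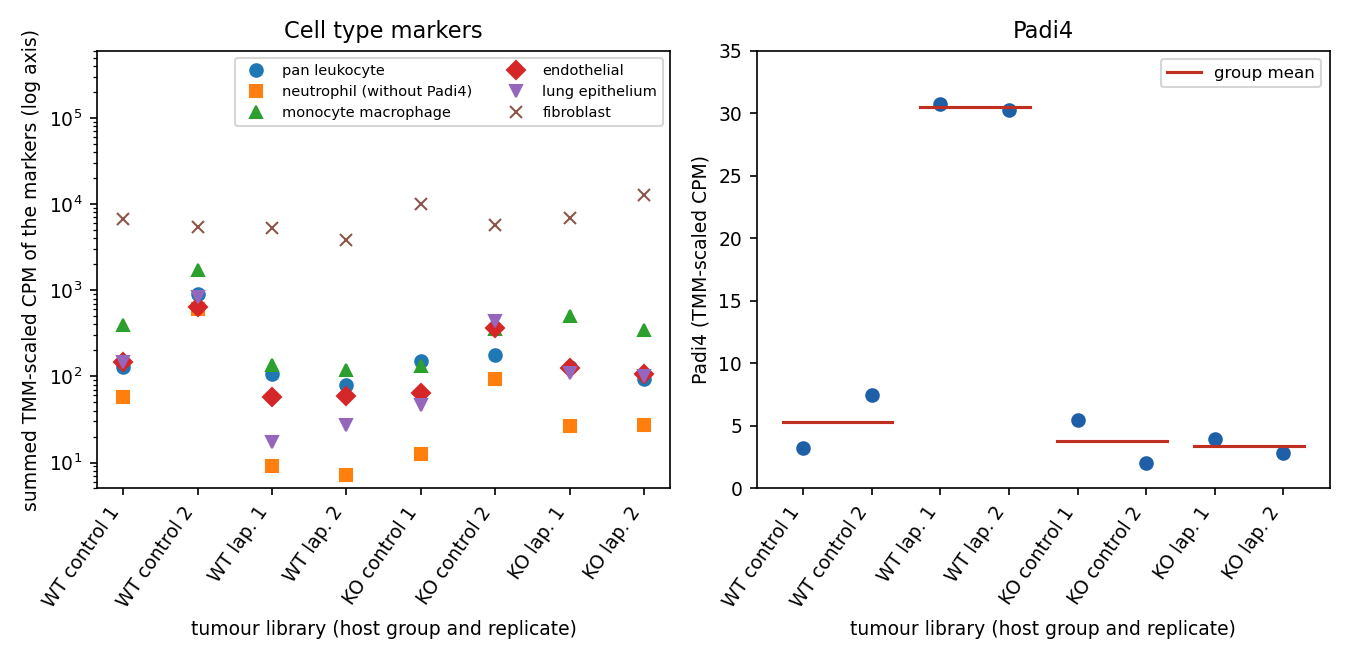
Summed TMM-scaled CPM of marker genes of other cell types in each of the 8 tumour libraries (left, log axis) and Padi4 in the same libraries with group means as lines (right). WT control libraries lie highest on average for lung epithelium markers (495 CPM) and WT laparotomy libraries lowest (22.1 CPM).

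The same comparison in KO hosts asked what laparotomy changes where the host cannot make PAD4. Ptgs1 (chromosome 2, 36230426 to 36252272), cyclooxygenase 1, rose from 5.41 ± 0.94 to 64.2 ± 18 CPM (SD, n = 2 each; log2 fold change 3.57 ± 0.46, adjusted p = 0.0322). Slitrk6, a neuronal membrane protein, rose by 5.03 ± 0.66, the growth factors Epgn and Nrg1 by 4.58 and 3.25, Phyh, which starts the breakdown of branched fatty acids, by 3.41 ± 0.42, and Syt13 by 3.39. Hbegf, a ligand of the EGF receptor, fell from 92.5 ± 19 to 22.2 ± 0.76 CPM (-2.06 ± 0.24, adjusted p = 0.0225). Without laparotomy, Hbegf was higher in KO than in WT hosts (log2 fold change 2.13) and Phyh lower (-3.63), both past the threshold. Ptgs1 stood at -2.96 in that comparison and did not pass. For Hbegf and Phyh the change thus starts from KO controls that differed from WT controls. Col8a1, a collagen VIII chain, fell by 3.14, Oaf fell by 2.69, Islr by 2.50, the sulfatase Arsi by 2.42 and the ganglioside synthase St3gal5 by 2.08. In all, 76 of 14615 genes passed, 50 higher and 26 lower, with 44 and 24 of them changed at least 2-fold and 2293 below an unadjusted p of 0.05.

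Cholesterol synthesis was higher as a list in KO hosts after laparotomy, with 23 of 24 log2 fold changes above 0, 1 gene past the threshold over all genes and 14 adjusted over the list alone (median 0.49; camera adjusted p = 3.65e-08; adjusted p = 0.235 with an estimated correlation). Mvd (chromosome 8, 122433601 to 122443422), which makes isopentenyl diphosphate, rose from 19.1 ± 3.5 to 41.9 ± 2.9 CPM (1.13 ± 0.17, adjusted p = 0.0377). Sqle stood at 0.70 ± 0.12 (adjusted p = 0.0559), Idi1 at 0.88 and Hmgcs1 at 0.77. Fatty acid synthesis had 1 of 21 higher over all genes and 6 adjusted over the list alone, none lower (median 0.31, adjusted p = 0.000968; adjusted p = 0.494 with an estimated correlation). Hsd17b12 rose from 158 ± 5.0 to 270 ± 18 CPM (0.77 ± 0.11, adjusted p = 0.034), and the desaturase Scd1 stood at 0.65 ± 0.11 (adjusted p = 0.0554). Between KO and WT controls, log2 fold changes were -0.60 for Hsd17b12, -0.42 for Scd1 and -0.39 for Sqle, none past the threshold. The fatty acid and cholesterol synthesis lists did not pass in that comparison either. In eicosanoid synthesis Ptgs1, Ptgs2 (2.95 ± 0.40) and the phospholipase Pla2g4a (2.12 ± 0.28) rose, 3 of 17 over all genes against 6 higher and 1 lower adjusted over the list alone (median 0.34, adjusted p = 0.048; adjusted p = 0.704 with an estimated correlation).

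Interferon response and MHC class I presentation were the lower lists in KO hosts. Both also passed, at the preset correlation, as lists higher in KO than in WT controls. Interferon response had 4 of 30 lower adjusted over the list alone and none over all genes (median -0.32, camera adjusted p = 0.000242; adjusted p = 0.824 with an estimated correlation), with Irf1, an interferon-induced regulator, at -0.60 ± 0.13. MHC class I presentation had 6 of 13 and none (-0.29, 0.0162; adjusted p = 0.704 with an estimated correlation), with the proteasome activators Psme1 and Psme2 both at -0.45. Higher lists with no gene past the threshold over all genes were NRF2 (median 0.28, adjusted p = 0.00356, 5 of 15 adjusted over the list alone), hypoxia (0.30, 0.0406, 4 of 17 higher and 1 lower), unfolded protein (0.16, 0.0459, 2 of 18 higher and 1 lower), and, with none adjusted over the list alone, epithelial genes (0.39, 0.0309), immediate early genes (0.36, 0.0406) and glycolysis (0.14, 0.0416). Their adjusted p was 0.824 with an estimated correlation, or 0.933 for immediate early genes. Host markers did not pass as lists, although 1 T and NK cell gene, Thy1 (2.58), passed over all genes and 3 of 11 fibroblast genes were higher and 2 lower adjusted over the list alone. Pan-leukocyte markers summed to 165 ± 20 CPM in KO controls and 110 ± 24 with laparotomy, endothelial markers to 215 ± 215 and 115 ± 12, and monocyte and macrophage markers to 241 ± 156 and 420 ± 109 (median 0.69, adjusted p = 0.0642).

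Median, mean and test differed in sign for 6 lists in KO hosts, none past the threshold, and 0 of 33 lists passed with an estimated correlation in camera (2 below an unadjusted p of 0.05; fry called 2). The count of 76 genes was 0 without KO control replicate 1 (edgeR, 2014 below an unadjusted p of 0.05), 138 without KO control replicate 2 and 1 without KO laparotomy replicate 2, while DESeq2 called 789 and limma-voom 38. The lists of cholesterol synthesis, fatty acid synthesis and interferon response, 3 of 11, passed with each library left out in turn. Eicosanoid synthesis did not pass without KO control replicate 1 (adjusted p = 0.375) or KO laparotomy replicate 2 (0.0776, median -0.04). MHC class I presentation (0.0911) and NRF2 (0.245) did not without KO control replicate 1. Hypoxia (0.244 and 0.392) and glycolysis (0.216 and 0.307) did not without KO control replicate 2 or KO laparotomy replicate 2. The epithelial, immediate early and unfolded protein lists each failed in at least 3 of the 4 fits.

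**Figure D3:**
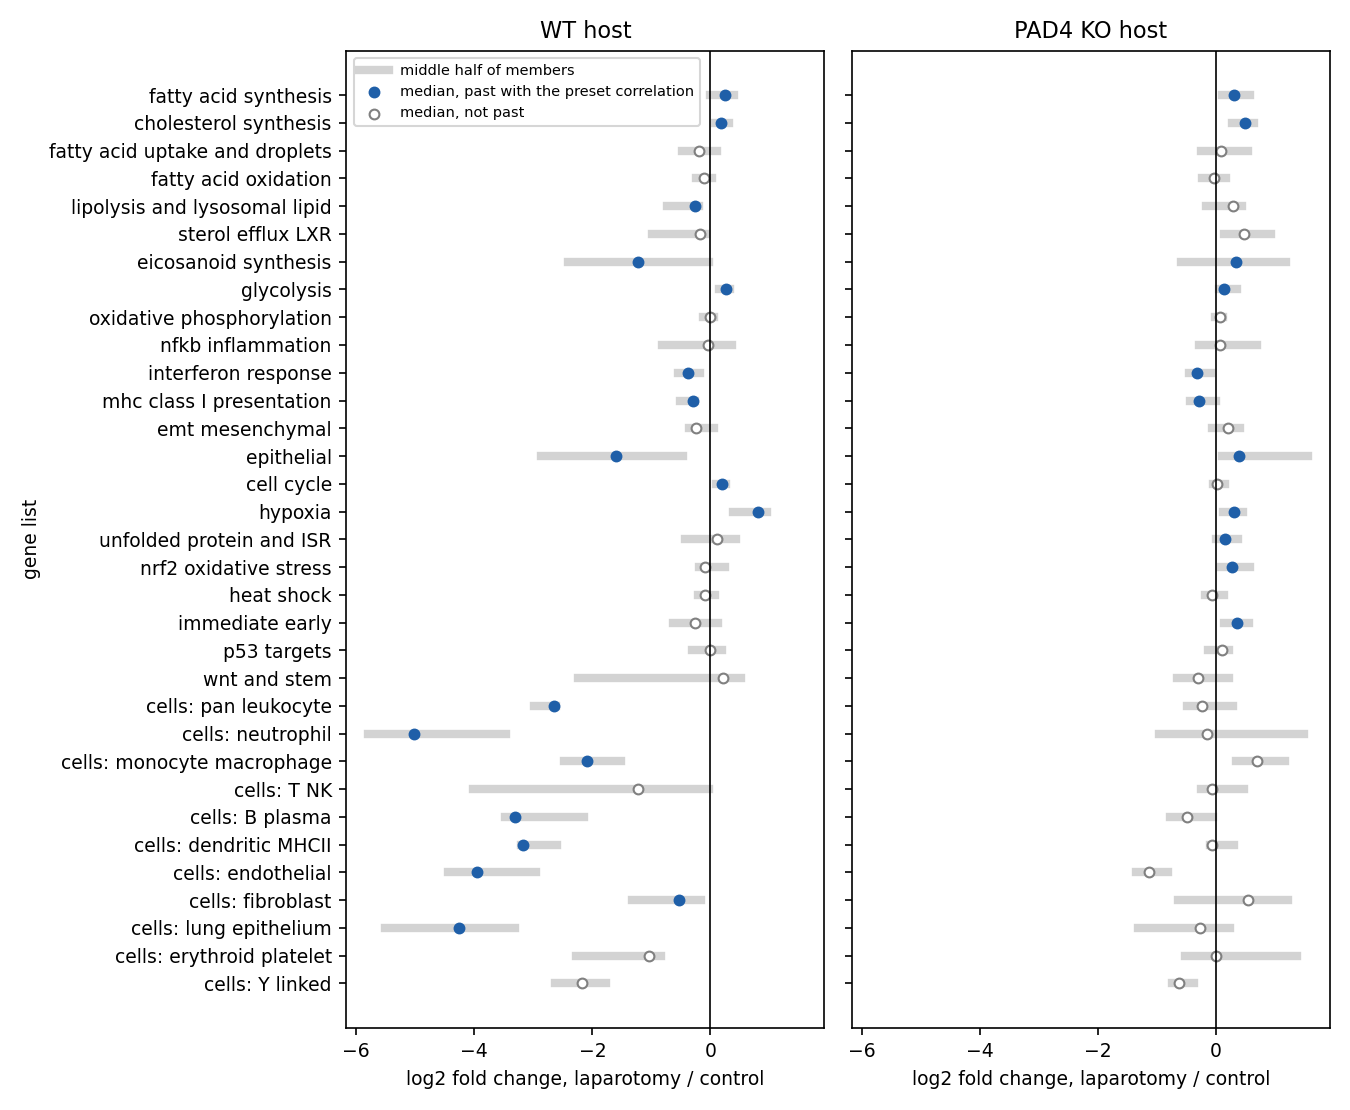
Log2 fold changes of each gene list between laparotomy and control tumours in WT hosts and in KO hosts (2 libraries per group); the point marks the list median, filled if the list passed with the preset correlation, and the bar spans the interquartile range of its members. The cholesterol synthesis median lies at 0.17 in WT hosts and 0.49 in KO hosts, and the hypoxia median at 0.81 and 0.30.

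The interaction asked whether laparotomy acts differently in KO and WT hosts. It uses the WT laparotomy libraries, so a separate run of that group cannot be told apart from a difference between hosts. It also holds the difference between KO and WT controls with the sign turned. Several genes named here, such as Phyh and Srgap3, passed the threshold between those controls too. Ptgs1 differed by 5.45 ± 0.63 (adjusted p = 0.021): its group means were 42.3 and 11.4 CPM in WT hosts without and with laparotomy, and 5.41 and 64.2 in KO hosts. Further genes with a higher effect in KO hosts were Slitrk6 (5.38), the skin protein Dmkn (5.18), cathepsin K (Ctsk, 5.09), the hyaluronan synthase Has1 (4.99 ± 0.49, adjusted p = 0.0134) and Phyh (4.76). Lower effects were found for the urea transporter Slc14a1 (-6.42), the transcription factor Ikzf2 (-4.31), Col8a1 (-3.93), Srgap3 (-3.71), Bicd1 (-3.62) and Met, the receptor of hepatocyte growth factor (-3.55). In all 99 genes passed, 60 with a higher and 39 with a lower effect in KO hosts, and 2803 were below an unadjusted p of 0.05.

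Eicosanoid synthesis was the lipid list that differed most clearly, with Ptgs1 and Alox5ap (2.83 ± 0.36) past the threshold, 2 of 17, and 7 adjusted over the list alone (median 1.81; camera adjusted p = 0.000704; adjusted p = 0.718 with an estimated correlation). Cholesterol synthesis had 6 of 24 higher and 1 lower adjusted over the list alone and none over all genes (median 0.37, adjusted p = 0.0306; adjusted p = 0.718 with an estimated correlation), with Mvd at 1.00 ± 0.24 (adjusted p = 0.0986). Lipolysis had 5 of 13 and none (0.76, 0.00909; adjusted p = 0.718 with an estimated correlation), with the lysosomal cholesterol carrier Npc2 at 0.76 ± 0.14. Fatty acid synthesis did not pass (0.11, adjusted p = 0.348; 2 higher and 2 lower of 21 adjusted over the list alone). Hypoxia was the only list past the threshold with a lower effect in KO hosts, with Kdm3a (-1.18) past over all genes and 4 of 17 lower and 1 higher adjusted over the list alone (-0.45, 0.0306; adjusted p = 0.718 with an estimated correlation).

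Host cell markers moved with the same contrast. Monocyte and macrophage (median 2.78, camera adjusted p = 7.59e-06), lung epithelium (3.38, 0.0005), neutrophil (4.59, 0.00173), endothelial (2.71, 0.0053), pan-leukocyte (2.50, 0.0306), dendritic (2.99, 0.0319), fibroblast (0.96, 0.0319) and B and plasma cell markers (2.78, 0.0349) were higher in the KO effect than in the WT effect. The epithelial list (2.79, 0.00173), mesenchymal genes (0.32, 0.0306) and NRF2 (0.31, 0.0306) were higher too. All of these had an adjusted p of 0.718 or 0.754 with an estimated correlation, where 0 of 33 passed in camera, 2 were below an unadjusted p of 0.05 and fry called 0.

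The count of 99 genes was 1 without WT laparotomy replicate 1, 0 without WT laparotomy replicate 2 (edgeR, 1716 below an unadjusted p of 0.05) and 8 without KO control replicate 1, and it was 344, 165 and 279 without WT control replicates 1 and 2 and KO control replicate 2. It was 53 without KO laparotomy replicate 1, 1158 in DESeq2 and 60 in limma-voom. Of the 15 lists, eicosanoid synthesis, epithelial, neutrophil, monocyte and macrophage, and lung epithelium passed with each library left out in turn. Cholesterol synthesis did not pass without WT control replicate 1 (adjusted p = 0.149), WT laparotomy replicate 1 (0.0596), KO control replicates 1 and 2 (0.0826 and 0.0656) or KO laparotomy replicate 2 (0.129). Lipolysis did not pass without WT control replicate 2 (0.104). Hypoxia did not pass without KO control replicate 1 (0.100) or KO laparotomy replicate 1 (0.130), and endothelial markers did not without KO control replicate 1 (0.113).

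**Figure D4:**
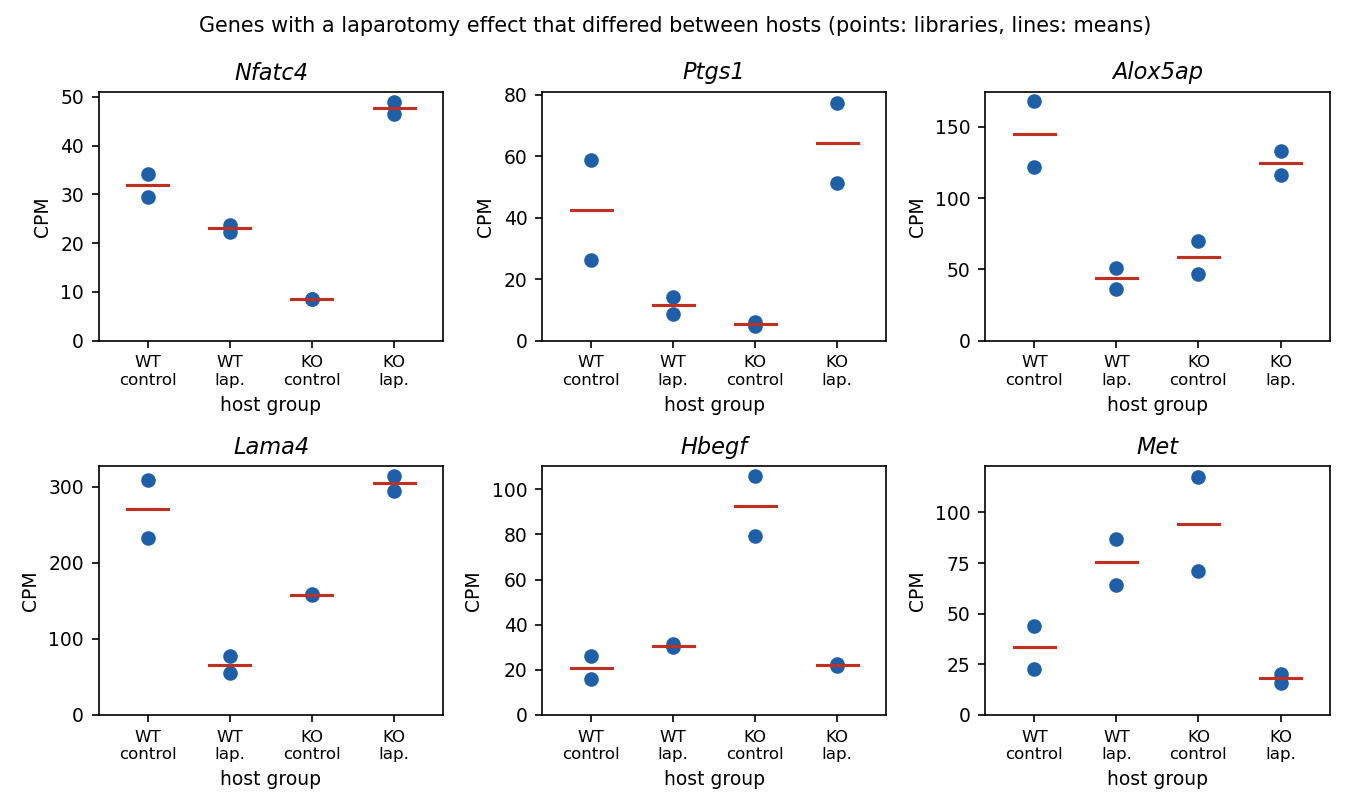
TMM-scaled CPM of 6 genes past the threshold for the interaction in each of the 8 tumour libraries (points, 2 per group), with group means as lines. Mean Ptgs1 was 42.3 CPM without and 11.4 CPM with laparotomy in WT hosts, and 5.41 and 64.2 CPM in KO hosts.

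The last 2 comparisons asked how tumour cells of KO and WT hosts differ without and with laparotomy. The comparison with laparotomy carries the same limit of a possible separate run of the WT laparotomy libraries. Without laparotomy, Nfatc4 (chromosome 14, 55823144 to 55833943), a calcium-regulated transcription factor, was lower in KO hosts, 8.61 ± 0.013 against 31.8 ± 3.3 CPM (SD, n = 2 each; log2 fold change -1.88 ± 0.14, adjusted p = 0.0156). Phyh was lower by -3.63, the surface protein Thy1 by -3.48, the Hedgehog transcription factor Gli1 by -2.32 and Mfap3l by -1.67. Olfr810 (-1.91) belongs to a large family of similar receptors, so its value is uncertain. Hbegf was higher in KO hosts (2.13 ± 0.24), as were Srgap3 (2.77), Ankrd1 (1.89), the cytokine receptor chain Il12rb1 (1.59), the kinase Nuak1 (1.47) and Myc (1.24 ± 0.13). In all 17 genes passed, 8 higher and 9 lower, with 2388 below an unadjusted p of 0.05. A fit of the compared groups alone called 0 (edgeR, 1575 below an unadjusted p of 0.05), and the pan-leukocyte covariate also lowered the count.

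Interferon response was higher in KO than in WT hosts without laparotomy (median 0.27, camera adjusted p = 0.00011; adjusted p = 0.661 with an estimated correlation): Irf1 rose by 1.07 ± 0.13 over all genes, 1 of 30, and 4 passed adjusted over the list alone. MHC class I presentation was higher too, with 4 of 13 adjusted over the list alone and none over all genes (0.16, 0.0115; adjusted p = 0.661 with an estimated correlation). Eicosanoid synthesis (median -1.01, adjusted p = 0.00776, 6 of 17 adjusted over the list alone), uptake and droplets (-0.61, 0.00966, 1 of 23) and lipolysis (-0.40, 0.00966, 2 of 13) were lower with no gene past the threshold over all genes, each with an adjusted p of 0.661 with an estimated correlation. Lower in the same libraries were monocyte and macrophage (-1.85, 2.35e-05), neutrophil (-3.16, 0.000348), epithelial (-1.34, 0.00822), B and plasma cell (-2.14, 0.013), pan-leukocyte (-2.22, 0.022) and T and NK cell markers (-2.21, 0.0433), at an adjusted p of 0.661 or 0.746 with an estimated correlation. Cholesterol synthesis (-0.07, 0.642) and fatty acid synthesis (-0.10, 0.147) did not pass. The count of 17 was 0 without KO control replicate 1 (edgeR, 1863 below an unadjusted p of 0.05), 218 and 46 without WT control replicates 1 and 2, 70 without KO control replicate 2, 784 in DESeq2 and 13 in limma-voom. Without WT control replicate 2 the interferon list (adjusted p = 0.221) and the pan-leukocyte list (0.923) no longer passed, and the T and NK cell median turned to 0.71. Of the 11 lists, those of neutrophils and of monocytes and macrophages passed with each library left out in turn. Eicosanoid synthesis (0.0685 and 0.0728), uptake and droplets (0.162 and 0.0728), lipolysis (0.309 and 0.0728) and MHC class I presentation (0.118 and 0.0728) did not without WT control replicate 2 or KO control replicate 1.

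With laparotomy, Lama4 was higher in KO than in WT hosts, 305 ± 13 against 66.2 ± 17 CPM (SD, n = 2 each; log2 fold change 2.20 ± 0.20). Fcgr2b was higher by 1.82 ± 0.18 and Adamts4, a protease of cartilage matrix, by 1.38 ± 0.14, each at an adjusted p of 0.0437, and these 3 were all that passed, with 1954 below an unadjusted p of 0.05. Immune and stromal lists were higher: interferon response (median 0.32, camera adjusted p = 1.42e-06, 7 of 30 adjusted over the list alone), MHC class I presentation (0.31, 2.94e-05, 9 of 13), NF-kB inflammation (0.55, 5.5e-05, 4 of 32), immediate early genes (0.59, 5.5e-05, 3 of 17) and mesenchymal genes (0.43, 0.000112, 6 of 22). Their adjusted p lay between 0.310 and 0.557 with an estimated correlation. Cholesterol synthesis (0.26, 0.000952, 2 of 24 adjusted over the list alone) and eicosanoid synthesis (1.15, 0.0032, 3 of 17) were higher as well, both at an adjusted p of 0.412 with an estimated correlation, and oxidative phosphorylation (0.17, 0.00892) at 0.557. Hypoxia (-0.69, 0.000348, 8 of 17 lower adjusted over the list alone) and glycolysis (-0.21, 0.0011, 1 of 18) were lower, at an adjusted p of 0.548 and 0.557 with an estimated correlation.

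Host markers were again higher beside these lists. Lung epithelium (median 2.26, camera adjusted p = 5.5e-05), fibroblast (1.30, 0.000335), monocyte and macrophage (1.03, 0.0011), endothelial (1.87, 0.00214), dendritic (1.66, 0.00819) and epithelial genes (1.32, 0.00895) were higher in KO than in WT hosts with laparotomy, at an adjusted p of 0.548 to 0.632 with an estimated correlation. Fibroblast markers summed to 9836 ± 4065 CPM in KO and 4551 ± 1019 in WT hosts. Between KO and WT hosts 0 of 33 lists passed with an estimated correlation in camera, without laparotomy (1 below an unadjusted p of 0.05, fry called 0) or with it (4 below, fry called 2). Counts with H2-D1, Gbp2 and Gbp3, members of families with near-identical copies, are uncertain. The count of 3 genes was 0 without either WT laparotomy replicate (edgeR, 762 and 944 below an unadjusted p of 0.05), 2 without either KO laparotomy replicate with none of the 3 among them, 567 in DESeq2 and 5 in limma-voom. Glycolysis did not pass without KO laparotomy replicate 1 (adjusted p = 0.0729). Oxidative phosphorylation did not pass without WT laparotomy replicate 1 (0.0720) or KO laparotomy replicate 2 (0.228), and monocyte and macrophage markers did not without KO laparotomy replicate 1 (0.155). Dendritic markers did not pass without WT laparotomy replicate 2 (0.117) or KO laparotomy replicate 1 (0.155). Epithelial genes did not pass without WT laparotomy replicate 2 (0.281) or KO laparotomy replicates 1 and 2 (0.214 and 0.127).

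Whether the culture response appears in tumours was tested with the 200 genes most clearly higher and the 200 most clearly lower with NET chromatin. In WT hosts with laparotomy 132 of the 200 NET-higher genes had a positive log2 fold change (median 0.11), with a Benjamini-Hochberg adjusted camera p of 0.0108 at the preset correlation and adjusted p = 0.602 with an estimated correlation. The NET-lower set had a median of 0.01 with 102 positive (0.512 preset, 0.951 estimated). In KO hosts the NET-higher set had a median of 0.01 with 106 positive (0.913 preset, 0.951 estimated) and the NET-lower set -0.09 with 78 positive (0.0398 preset, 0.951 estimated). Across 11574 genes, which are not independent replicates, fold changes with NET chromatin and with laparotomy correlated at a Pearson r of -0.04 and a Spearman rho of 0.09 in WT hosts and 0.06 and 0.07 in KO hosts. Across 14615 genes the WT and KO laparotomy effects, which share no libraries, correlated at 0.04 and -0.04.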

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

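The tests of S100a8 and S100a9 against Mmp8, of the host markers without 1 library, of the sample-sheet numbers, of the other neutrophil markers and of the MC-38 share were chosen only after the result was seen. In the 3 NET cultures 9.86% ± 1.52 of reads were unmapped and 22.6% ± 1.19 matched no counted gene feature. Both were above the 6.55% ± 0.56 and 17.9% ± 0.33 of the control cultures (exact permutation p = 0.1, the smallest that 3 against 3 libraries allow). The gene tests do not use these read classes. Reads without a feature may lie in introns as well as between genes, and the counts do not tell which. Genomic DNA carried with the NET chromatin would add reads to genes that these cells do not use. The 1455 olfactory and vomeronasal receptor genes argue against it, with 6.97 ± 0.84 CPM in NET and 7.88 ± 0.84 CPM in control cultures, a difference of -0.911. Not every gene of the set is silent: Olfr810 had a mean log2 CPM of 3.83 over the tumour libraries. A few expressed members could therefore weigh on the sum in culture, and how it was spread over the genes was not tested. Neutrophil RNA carried with the NETs would bring S100a8 and S100a9 above all, if it is made up as in intact neutrophils. They gained 2.19 CPM together against 6.47 (SD 1.09 in NET cultures) for Mmp8, which went from 1 to 209 counts (ratio 218, counting interval 38.8 to 8663). In WT control replicate 2, rich in neutrophil markers, they stood at 144 and 244 CPM and Mmp8 at 26.0. Under that assumption, neutrophil RNA is argued against as the main source of Mmp8. Some neutrophil transcripts did appear beside it: S100a9 had 0 counts in each control culture and 8, 7 and 28 in the NET cultures. For the other leukocyte transcripts neutrophil RNA stays open. A response of the cells to NET chromatin, which the design names, may explain the leukocyte transcripts. RNA of other cells carried with the chromatin stays open too: Y-linked genes were at 0 in the 3 controls and at 0.122, 0.674 and 0.102 CPM in the NET cultures, and the source of the neutrophils is not given in the sources used here. The Y-linked values rest on a few reads each. For scale, 5, 8 and 32 counts of Ptprc made 0.612, 1.35 and 1.63 CPM in these NET cultures. The 10 splits of the 6 cultures into 3 and 3 are too few for a share under 0.05; the real split gave 6363 genes (1 of 10 splits with as many) and the highest other 0.

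The laparotomy effect differed between KO and WT hosts, by the interaction term, for 99 genes and 15 gene lists. This term also holds the gap between KO and WT controls, with the sign turned. Phyh, Thy1, Gli1, Nfatc4, Mfap3l and Olfr810 were lower in KO than in WT controls. Srgap3, Hbegf, Ankrd1, Nuak1 and Myc were higher there, and each of these genes passed the threshold. Lama4, Fcgr2b and Adamts4 passed between hosts with laparotomy instead. The share of each part was not tested. The lists passed camera at the preset correlation, and 0 of 33 passed with an estimated correlation. Several of the 15 were lists of host cell markers. On the log2 scale, KO minus WT, the difference was 5.45 for Ptgs1, 5.38 for Slitrk6, 5.18 for Dmkn, 5.09 for Ctsk, 4.99 for Has1, 4.76 for Phyh, 4.16 for Thy1, 3.87 for Olfr810, 3.11 for Gli1, 2.97 for Lama4, 2.93 for Nfatc4 and 2.83 for Alox5ap. It was 2.38 for Fcgr2b, 2.35 for Mfap3l, 1.72 for Crip1, 1.58 for Adamts4 and 1.35 for Ecscr. Lower effects in KO hosts were -1.18 for Kdm3a, -1.40 for Myc, -1.61 for Nuak1, -2.31 for St3gal5, -2.59 for Hbegf, -3.40 for Oaf, -3.46 for Ankrd1, -3.55 for Met, -3.62 for Bicd1, -3.71 for Srgap3, -3.93 for Col8a1, -4.31 for Ikzf2 and -6.42 for Slc14a1. The count was 1 and 0 without WT laparotomy replicates 1 and 2 (edgeR, 1716 below an unadjusted p of 0.05 without replicate 2), 8 without KO control replicate 1, 53 without KO laparotomy replicate 1, 344 and 165 without WT control replicates 1 and 2, and 279 without KO control replicate 2, against 1158 in DESeq2 and 60 in limma-voom.

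Host cell markers were lower in WT laparotomy than in WT control libraries, which the sort for green fluorescent cells would remove if it were complete: the median log2 fold change of 104 markers was -2.66, with 99 below 0, and mean levels were 638 and 40.1 CPM for Lyz2 and 211 and 3.599 for Sftpc in WT control and WT laparotomy libraries. The filter on counts let 31 of the markers through in the cultures too. WT control replicate 2, with the highest marker levels, is argued against as the whole cause for the markers as a set. Without it the median was -1.30 with 93 of 104 below 0 (-3.48 and 104 of 109 without replicate 1). WT control replicates 1 and 2 held 211 and 1065 CPM of Lyz2 and 44.5 and 378 of Sftpc. Not every cell type was lower than in replicate 1. T and NK cell markers summed to 31.3 CPM in replicate 1 and to 52.3 and 44.6 in the WT laparotomy libraries. Ptprc stood at 18.7 against 22.6 and 16.5 CPM. Lung epithelium markers summed to 148 CPM in replicate 1 against 17.3 and 27.0. A separate sequencing run of the WT laparotomy libraries cannot be told apart from the laparotomy. Their 2 sample-sheet numbers are shared with WT control replicate 2 and KO control replicate 1. A single sheet with a number per library could therefore not hold all tumour libraries. The labels give no run. Laparotomy may have lowered the share of host cells in the sorted fraction, and the purity of the sorts is not given in the sources used here.

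Padi4 stood at 30.7 and 30.3 CPM in the WT laparotomy libraries and at 2.08 to 7.49 in the other 6 tumour libraries. It did not pass the threshold in edgeR with the tumour libraries alone (log2 fold change 2.48 ± 0.52). DESeq2 called it, as did the fit of all 14 libraries, which shares its spread with the less variable cultures. Neutrophils, the marker list that holds Padi4, are argued against: the 13 other markers summed to 9.20 and 7.21 CPM in WT laparotomy and 57.5 and 603 in WT control libraries, a mean difference of -322, with S100a9 at 1.80 and 134 CPM on average. A larger share of MC-38 RNA as the whole cause is argued against by 330 genes of the cultured cells, whose upper quartile was 0.61 (median 0.24, 222 above 0). The first bounds for that test, a median of 0.5 or of 0, were set before its result was seen and decided nothing, and the quartile was taken afterwards. A higher Padi4 level in the cancer cells of WT hosts after laparotomy remains a candidate explanation, and whether these libraries came from a separate run is not given in the sources used here.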

How the results depend on the processing

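The test of library totals was chosen only after the results were seen. The NET comparison (6363 genes) stayed between 5591 (DESeq2) and 6629 (no filter on low counts) in every alternative with all 6 cultures but the fit of all 14 libraries, with 3716, and library totals gave 6417, 1640 higher and 4777 lower. The fit of all 14 libraries shares its spread between the tumours and the less variable cultures, so its tumour counts may be too high. The tumour counts depend on the tool, the filter and the libraries fitted together, and the cause was not tested. For laparotomy in WT hosts, laparotomy in KO hosts, the interaction, and KO against WT without and with laparotomy (8, 76, 99, 17 and 3 genes), they were 166, 278, 399, 196 and 152 without a filter on low counts, 1450, 1132, 1596, 1046 and 712 with all 14 libraries, and 1207, 789, 1158, 784 and 567 in DESeq2. With limma-voom they were 21, 38, 60, 13 and 5. A pan-leukocyte covariate gave 0 (edgeR, 1141 below an unadjusted p of 0.05), 162, 56, 2 and 28. A fit of the compared groups alone gave 14 and 54 for laparotomy in WT and KO hosts, 0 (edgeR, 1575 below an unadjusted p of 0.05) and 220 between hosts. RLE size factors gave 13 genes in WT hosts; the other RLE counts and all counts from the strand-specific column were within 1.5 times. With an estimated correlation 0 lists passed in camera in each of the 6 comparisons.

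With the replicate block, genes fell to 0 for laparotomy in WT hosts (edgeR, 2511 below an unadjusted p of 0.05), 56 for the interaction, 0 for KO against WT without laparotomy (2156 below) and 1 with it, while laparotomy in KO hosts had 59. After removal of group means, culture libraries of different groups correlated at -0.03 to 0.09 with the same number and at -0.17 to 0.09 with another. The numbers thus gave no sign of pairing in culture. In tumours the values for the same number were -0.12 to 0.36. With 2 libraries per group, those for the other number are the same with the sign turned, so pairing in tumours cannot be decided.

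The Padi4 log2 fold change turned sign to 0.0505 for KO against WT without laparotomy with the pan-leukocyte covariate and to 0.000333 for laparotomy in KO hosts with limma-voom; the cause was not tested, and neither passed the threshold in any alternative. In WT hosts with laparotomy the NET-lower median turned to -0.0119 with RLE size factors and -0.0203 with 100 genes per direction. With the preset correlation of 0.01 the NET-higher set passed (0.114, adjusted p = 0.0108), as did the NET-lower set in KO hosts (-0.0923, adjusted p = 0.0398); at this preset their adjusted p was 0.0858 and 0.182 with 100 genes and 0.00308 and 0.0719 with 500. Over the alternatives with an estimated correlation it was 0.345 to 0.990 and 0.130 to 0.990. The cause of these changes was not tested.

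With each library left out in turn, a lone sample left in a tumour group was assumed to vary like the other groups. The NET count was 5006 to 6311, and 6344 to 6363 of the 6363 genes kept their direction. All called genes of the tumour comparisons kept theirs. Each of these fits reuses libraries that made the calls, so a kept direction is no independent support. Laparotomy in WT hosts gave 0 to 512 genes (512 and 13 without WT control replicates 1 and 2, with 8 and 3 of the 8 among them, 0 without either WT laparotomy replicate; edgeR, 1074 and 1304 below an unadjusted p of 0.05) and laparotomy in KO hosts 0 to 138 (0 without KO control replicate 1, 2014 below; 138 without control replicate 2; 52 and 1 without laparotomy replicates 1 and 2). The interaction gave 0 to 344 (0 without WT laparotomy replicate 2, 1716 below; 1 without replicate 1; 344 and 165 without WT control replicates 1 and 2; 8 and 279 without KO control replicates 1 and 2; 53 and 97 without KO laparotomy replicates 1 and 2). KO against WT gave 0 to 218 without laparotomy (0 without KO control replicate 1, 1863 below; 70 without replicate 2; 218 and 46 without WT control replicates 1 and 2) and 0 to 2 with it (0 without either WT laparotomy replicate, 762 and 944 below; 2 without either KO laparotomy replicate, with 0 of the 3 among them, so none of the 3 passed with any of these 4 libraries left out). Lists past the threshold numbered 8 to 15 in the interaction (8 without KO control replicate 1, 9 without KO laparotomy replicate 2) and 7 to 9 for laparotomy in KO hosts (7 without either of these). They numbered 4 to 17 for KO against WT without laparotomy (4 without KO control replicate 1, 17 and 6 without WT control replicates 1 and 2). Those that passed each time were 7 of 7 for NET, 11 of 18 for laparotomy in WT hosts, 3 of 11 in KO hosts, 5 of 15 in the interaction, and 2 of 11 and 11 of 16 between hosts. Padi4 ranged from -0.0689 to 0.0135 with NET chromatin, -1.40 to 0.238 for KO against WT without laparotomy and -0.687 to 0.714 for laparotomy in KO hosts. The NET-lower median in WT hosts was -0.00588 to 0.0329, and in KO hosts the NET-higher median was -0.0886 to 0.0265 and the NET-lower median -0.197 to 0.0271. On simulated counts at the real depth, 71.6% of 1.5-fold changes were called for NET, 5.97% for laparotomy in WT hosts and 0% for the interaction, so changes of this size are mostly missed in tumours.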

Other observations

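The genes below other than Il33, and the comparison of culture with tumour levels, were chosen only after the results were seen. The receptor of IL-33 changed with its ligand in culture: Il1rl1, which encodes it, had the smallest adjusted p of the NET comparison (log2 fold change 2.34 ± 0.07, adjusted p = 1.21e-13), and Il33 itself rose by 5.12 ± 0.24. In the sorted tumour libraries Il33 stood at 307 ± 84 CPM in WT control, 159 ± 32 in WT laparotomy, 172 ± 30 in KO control and 149 ± 1.5 in KO laparotomy libraries (SD, n = 2 each). Il1rl1 stood at 296 ± 43, 1179.8 ± 8.7, 484 ± 165 and 1099.9 ± 967 CPM in the same groups, and neither gene passed the threshold in a tumour comparison. The WT control group also had the highest mean of summed lung epithelium markers (495 CPM). Whether cancer cells or host cells in the sorted fraction gave these transcripts was not tested. Cyr61, a matrix protein induced by YAP, rose by 1.89 ± 0.07 with NET chromatin (adjusted p = 1.07e-11) and the kinase Plk2 by 1.44 ± 0.06 (adjusted p = 2.68e-11), while Col6a1, a collagen VI chain like Col6a2, stood at -1.98 ± 0.08 (adjusted p = 1.07e-11).

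Culture and tumour libraries were scaled separately and not tested against each other. Col6a3 had a mean of 19.2 CPM in the 6 cultures and 5730 in the 8 tumour libraries, and Col1a1 2.03 and 1428. Markers of host cells were also higher in tumour libraries: fibroblast markers, a list that holds Col1a1 and Col1a2, summed to 148 CPM in control and 166 in NET cultures and to 4551 to 9836 in the 4 tumour groups, and pan-leukocyte markers to 5.20 and 16.7 against 91.9 to 511. Whether the cancer cells or host cells in the sorted fraction gave the transcripts below was not tested. At least 10 CPM in every tumour library and below 0.5 in every culture was found for 23 genes, among them Col1a2 (mean 244 CPM in tumours), Lama4 (199.98), Col5a2 (173), Nrep (119), Ednra (115), Angptl4 (98.0), Bgn (92.0) and Tgfbi (91.4). The reverse held for 5 genes: Ptprtos (53.3 CPM in cultures), Rhox2h (30.0), Atp8b3 (21.95), Ovol2 (20.7) and Nfasc (15.6). Padi4 averaged 66.2 ± 2.96 CPM in cultures and 10.8 ± 12.3 in tumours.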
